A study of Kluyveromyces lactis with 18 samples.

How the data were processed

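Kluyveromyces lactis was grown on methionine, cystine or sulfate as the sulfur source, at a high and at a low concentration, per the labels with a ratio of 1000. Each source had 3 biological replicates. In each replicate the total RNA of the high and the low culture was labelled with Alexa 647 and Alexa 555 and hybridised to the same array, and a second array carried the same pair with the dyes exchanged. The series therefore held 18 arrays, in 3 sources of 6. The replicate numbers did not pair replicates of different sources: between sources, replicates of the same number matched best for 3 of 9 replicates, and the correlations of the 9 possible pairs, after removal of each source's mean, ran from -0.21 to 0.25. A replicate was treated as the independent unit and its arrays as technical repeats.

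The arrays were custom Agilent 2-colour oligonucleotide arrays with 11168 features. Of these, 10452 spots carried probes for 5081 genes, with 1 probe per gene and usually 2 spots per probe, and 180 spots were negative controls. Probes were 40, 50 or 60 bases long. Per the file headers, the spot files of the authors were made with Feature Extraction 9.1.3.1 and hold raw intensity values of spot and local background, intensity values processed by background subtraction and dye normalization, a log10 ratio of the processed signals, and other columns with flags of 0 or 1 per spot. The deposited table of values per array is on a log2 scale and was tested against the spot files. On each of the 18 arrays a smooth function of brightness explained between 0.998 and 1 of its variance, and its median ran from -1.64 to 1.80. The deposited table therefore holds the brightness trend of the log2 ratio on each array and not normalised ratios, and it was used only in an alternative that subtracts this trend from the raw ratios. No columns of other series were held. The genome build behind the probes is not given in the sources used here. A RefSeq table of the assembly ASM251v1 served for gene names only: 5069 of the 5081 array identifiers matched a locus tag and 12 did not. Of the genes tested, 2823 had a symbol and 736 are named by their array identifier.

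Mean spot signals and local median backgrounds were read in R 4.3.3 with the package data.table (version 1.17.8). With limma 3.58.1, backgrounds were corrected by normexp with an offset of 50, and log2 ratios were normalised within each array by loess on spot brightness. Control spots and spots with an outlier flag had no weight in the loess curve, and spots with such a flag, 0.879% of the gene spots, were removed. No gene spot was saturated. Ratios were turned to low over high, spots of a gene were averaged, and the arrays with exchanged dyes were averaged to 1 value per replicate. A gene was tested when it was well above background in the same culture type on at least 4 of the 6 arrays of a source, which left 3559 genes, of which 38 lacked at least 1 replicate because of removed spots. A linear model with 1 coefficient per source was fitted by limma to the 9 replicate values, with empirical Bayes moderation (6 residual degrees of freedom, 3.25 prior degrees of freedom). All tests were two-sided. Adjusted p values are limma's after the Benjamini-Hochberg correction over all genes tested, and a gene was called at an adjusted p under 0.05. The number of called genes that also changed at least 2-fold is given beside each count. Differences between sources were tested as contrasts of the coefficients in the same fit. Genes changed in more than 1 source were counted per direction and set against the number that independent lists would share, with Fisher's exact test adjusted over the 6 overlaps.

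Where a called transcript was well above background on none of a source's high-culture arrays, its fold change is given as a lower bound. This is a bound on the estimate and takes in no sampling error, so the true change can be smaller. The log2 ratio beside it is that of the model and is no bound. Where it was above background on 1 to 3 of the 6, the ratio of the model is given with no fold change and is no exact size (in cystine ILV3, ERG1, LYS12, TES1, ERG10, PEX11 and CTA1, and in sulfate OYE2, among others). The same holds for the log2 ratios of transcripts that were not called and not above background in the high culture: MET4, MET30 and FMO1 in methionine, and CYS4, AGP3, ERG10, MET16, MET22, SAM3, TRP1 and MET30 in sulfate. The bound sets the level in the low culture against the lowest level that any gene well above background had in the high culture of the same array, or against the transcript's own level there where that was higher. For JLP1 in sulfate its own level was the higher on each array, so no bound apart from the ratio of the model is given. Fold changes are those of normexp and loess, and their size differs with other processing. Errors are standard errors from the shared spread. For values that rest on 3 replicates the number of replicates is given once. The number of arrays limits the precision. On simulated data with this design and a spread pooled over the sources, 93 to 96% of genes changed by 1 on the log2 scale were called. So were 100% of those changed by 2, and between 5 and 14 of 3359 unchanged genes. The simulation held as many rises as falls and a dye trend with brightness. It held no trend of brightness between the low and the high culture and no source's own spread. Its shares are therefore no measure of the power in a given source.

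The samples, tests, alternatives, 34 gene lists and the rule for named genes were fixed before the data were examined. The rule named the 5 largest rises and the 5 largest falls per source among called genes that carry a symbol, moved the same way in all 3 replicates and were well above background. It also named up to 4 members with the smallest adjusted p of each called list, a panel of 24 sulfur genes in every source, and the 5 largest differences between sources in each direction. Of the panel, 18 genes were tested, STR2 was on the array and did not pass the brightness filter, and MET5, SAM1, SUL1, BDS1 and MET32 had no match by symbol on the array. Genes with no symbol that are named below were chosen after their values were seen.

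Lists of at least 3 tested genes were tested with limma's camera on the moderated statistics with a preset inter-gene correlation of 0.01, adjusted over the 34 lists per comparison. The same test with an estimated correlation stands beside it, and the closing section gives the counts by limma's fry. The sulfur lists were sulfate uptake and assimilation, synthesis of homocysteine with methionine and S-adenosylmethionine (SAM), cysteine synthesis and transsulfuration, sulfur amino acid and peptide transport, use of other sulfur compounds, sulfur regulators, and glutathione metabolism. Lists near to them were thioredoxin with glutaredoxin and peroxide defence, iron-sulfur cluster assembly, iron and copper uptake and iron regulon, methionine and aromatic amino acid catabolism (the Ehrlich pathway), methionine salvage and polyamines, thiamine and biotin, and folate and one-carbon metabolism. The lists of other metabolism were purine synthesis, other amino acid synthesis, nitrogen catabolism and ammonium, glycolysis and ethanol formation, the citric acid cycle, the respiratory chain and ATP synthase, gluconeogenesis with the glyoxylate cycle and acetate, peroxisome and beta-oxidation, ergosterol synthesis, phosphate, and lactose and galactose use. The remaining lists were cytosolic ribosomal proteins, ribosome biogenesis, mitochondrial ribosomal proteins, general stress response, chaperones and heat shock, proteasome, autophagy, mating and meiosis, and histones. The list named citric acid cycle was wider than the cycle itself. It also held related enzymes such as MDH2, MDH3 and IDP1, and genes of pyruvate metabolism.

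The alternatives fixed in advance were no background correction, Agilent's processed signals, median centring in place of loess, an equal spread of every array, no brightness filter, a strict brightness filter, each source fitted alone, all 18 arrays in 1 fit with a dye term, each dye orientation alone, the deposited trend, slide as a block, the replicate number as a block, robust moderation, an estimated correlation, and leaving out each replicate. Array quality weights, keeping the spots with outlier flags, single slides, and leaving out each of 2 arrays with raised negative controls were added after seeing the data. Of the tested genes, 29 shared their probe sequence with another gene, and among the genes named below only KLLA0B00242g did.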

Results

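The series measured transcript levels in Kluyveromyces lactis, a lactose-using yeast, grown for 10 generations with methionine, cystine (the disulfide of cysteine) or sulfate as the sulfur source. The labels frame it as an exploration of sulfur metabolism under high against low sulfur. High cultures held 10 mM methionine, 1 mM cystine or 0.1 mM sulfate, and low cultures held 10 µM methionine, 1 µM cystine or 0.1 µM sulfate, so that the sources differed in concentration as well as in kind. Each source had 3 biological replicates of 2 arrays each. Values are log2 ratios of the low over the high culture, with the standard error after ±, and rest on n = 3 replicates unless another n is given. Of the 5081 genes on the array, 3559 were bright enough to be tested.

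The share of genes well above background was 42.2 to 58.8% in high methionine and 59.0 to 87.4% in low methionine over the 6 arrays. It was 41.1 to 80.5% in high cystine and 51.1 to 69.6% in low cystine. The sulfate arrays were dimmer, at 7.42 to 63.5% in high sulfate and 27.0 to 62.5% in low sulfate. Across genes, which are not independent replicates, pairs of replicates correlated at r = 0.468 to 0.564 in methionine, 0.692 to 0.790 in cystine and 0.509 to 0.771 in sulfate. Pairs between sources reached 0.743: methionine replicate 2 correlated at 0.743 with sulfate replicate 2 and at 0.707 with cystine replicate 3, above any pair within methionine. On the unswapped array of sulfate replicate 3 the red negative controls had a median signal of 282, against 51.8 to 60.8 on the other sulfate arrays, and on the unswapped array of cystine replicate 3 it was 110.3. The methionine and cystine arrays shared slides and a scan session, and the sulfate arrays came from other slides in another session, so sulfate and session cannot be told apart.

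**Figure D1:**
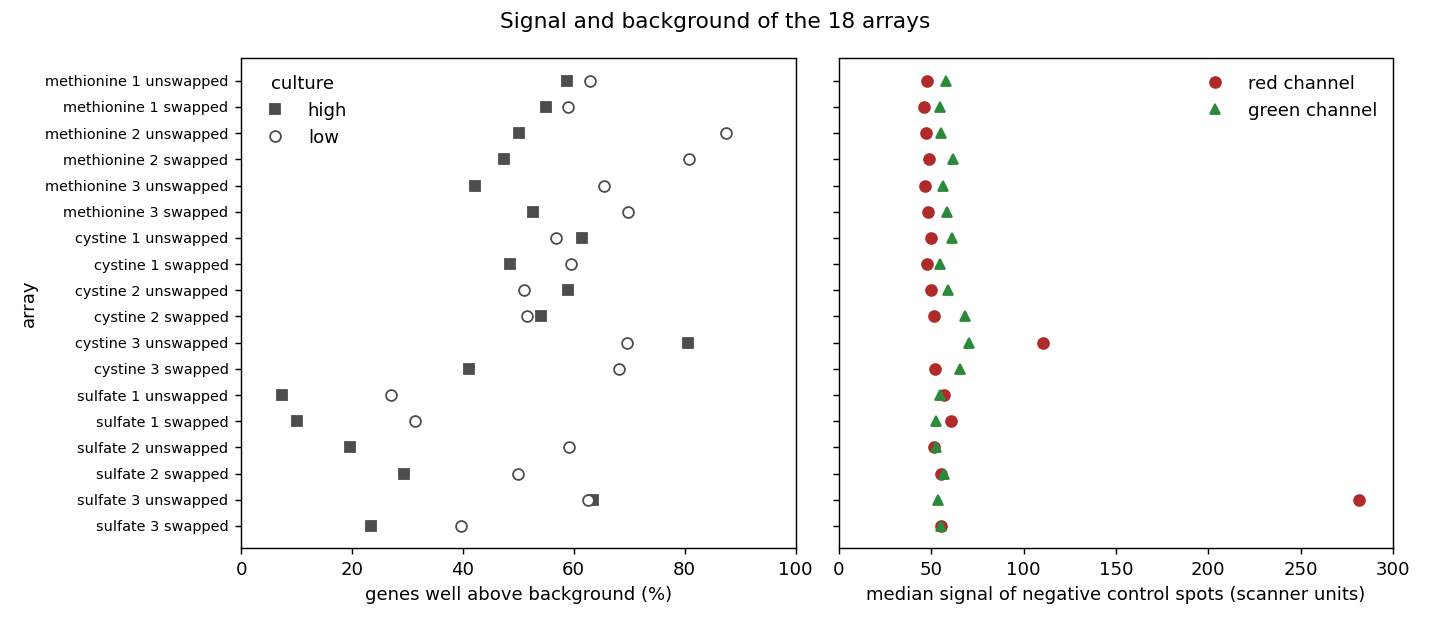
Signal of the 18 arrays. The left panel gives the share of genes (%) well above background in the high (squares) and low (circles) culture of each array, and the right panel gives the median signal (scanner units) of the negative control spots in the red (circles) and green (triangles) channel. The share in high sulfate was as low as 7.42%, and the red negative controls reached 282 on the unswapped array of sulfate replicate 3.

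Transcripts for taking up and reducing sulfate rose in low methionine. MET14, which encodes adenylylsulfate kinase, rose (4.46 ± 0.47, adjusted p = 0.00186, above background in high methionine on 3 of 6 arrays). MET10, a subunit of sulfite reductase, rose 8.54-fold (3.09 ± 0.24, adjusted p = 0.000374, and 4.50 with processed signals). MET3, which encodes ATP sulfurylase, and SUL2, a sulfate permease, were not above background in high methionine and rose at least 9.98-fold (3.63 ± 0.35) and at least 10.2-fold (3.60 ± 0.37). MET16, which encodes phosphoadenylylsulfate reductase, rose at least 1.85-fold (1.13 ± 0.18, adjusted p = 0.0123). All 7 measured genes of sulfate uptake and assimilation rose, 7 of them also when adjusted over the list alone, with a list median of 3.09 (camera adjusted p = 2.0e-39, and adjusted p = 6.9e-10 with an estimated correlation).

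Some genes that turn reduced sulfur into amino acids rose with them. MET17, which encodes O-acetylhomoserine sulfhydrylase, rose 55.5-fold (5.79 ± 0.49, n = 2, adjusted p = 0.00464, and 6.96 with processed signals). MET6, methionine synthase, rose 6.82-fold (2.77 ± 0.27), and MET2, homoserine acetyltransferase, rose (2.61 ± 0.30, above background in high methionine on 3 of 6 arrays). In the list of homocysteine, methionine and SAM synthesis 3 of 8 measured genes rose, and 5 rose and 1 fell when adjusted over the list alone (median 0.57, camera adjusted p = 1.4e-09, and 7.6e-07 with an estimated correlation). CYS3, cystathionine gamma-lyase, rose 4.40-fold (2.14 ± 0.13, adjusted p = 0.000153). CYS3 was the called gene of the 3 in cysteine synthesis and transsulfuration (3 rose adjusted over the list alone, median 1.05, camera adjusted p = 1.5e-12, and 2.9e-11 with an estimated correlation). The other members were STR3, cystathionine beta-lyase, at 1.05 ± 0.23 (adjusted p = 0.0578) and CYS4, cystathionine beta-synthase, at 0.84 ± 0.35 (adjusted p = 0.327).

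Genes for transport and scavenging of sulfur compounds were also among those called. The methionine permease gene MUP1 rose (2.56 ± 0.31, above background in high methionine on 1 of 6 arrays). The oligopeptide transporter gene OPT1 rose at least 3.72-fold (2.20 ± 0.31), and the cysteine transporter gene YCT1 rose 3.25-fold (1.70 ± 0.32). These were the 3 called of 8 genes of sulfur amino acid and peptide transport (6 rose and 1 fell adjusted over the list alone, median 0.62, camera adjusted p = 3.8e-07, and 0.00288 with an estimated correlation). JLP1, a dioxygenase that releases sulfite from sulfonates, rose at least 8.82-fold (3.48 ± 0.39, adjusted p = 0.00325). JLP1 was the 1 called of 3 genes for the use of other sulfur compounds (2 rose adjusted over the list alone, median 0.55, camera adjusted p = 9.1e-05, and 0.00663 with an estimated correlation), with SEO1 at 0.55 ± 0.26 and FMO1 at 0.29 ± 0.11. The median of these 3 was 0.91 and 0.36 without methionine replicate 2 and 3.

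Of 13 glutathione genes 3 rose: DUG3 (1.58 ± 0.25) and DUG2 (at least 1.86-fold, 0.97 ± 0.13), of the enzyme that degrades glutathione, and GSH1, the first enzyme of its synthesis (1.27 ± 0.23). That list shifted up (median 0.12, 3 rose adjusted over the list alone, camera adjusted p = 0.00318, and 0.012 with an estimated correlation). In folate and one-carbon metabolism 2 of 18 genes rose, SHM2, serine hydroxymethyltransferase (1.26 ± 0.26), and GCV2, glycine decarboxylase (0.89 ± 0.12, above background in high methionine on 1 of 6 arrays), and 5 rose adjusted over the list alone (median 0.13, camera adjusted p = 0.00318, and 0.0453 with an estimated correlation). Of the sulfur regulators, MET28 rose at least 1.41-fold (0.68 ± 0.10, adjusted p = 0.00772), while MET4 was at 0.35 ± 0.20, MET30 at 0.17 ± 0.12 (-0.09 with median centring) and CBF1 at 0.17 ± 0.21. The list of 4 regulators was called (1 rose adjusted over the list alone, camera adjusted p = 0.00784), but not with an estimated correlation (adjusted p = 0.0788). The list of thioredoxin, glutaredoxin and peroxide defence was also called (median 0.28, 4 rose and 1 fell of 19, 4 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.00543), but not with an estimated correlation (adjusted p = 0.187). Among its members the superoxide dismutase gene SOD1 rose (0.95 ± 0.18), as did OYE2, an NADPH oxidoreductase (0.91 ± 0.17), while the catalase gene CTA1 fell (-0.63 ± 0.12, and -0.17 with an adjusted p of 0.348 with median centring and -0.87 with 0.268 with processed signals). The peroxiredoxin gene PRX1, also among the 4, had a value in 1 replicate alone (3.47), with the spread taken from the other sources. The glutathione median was 0.25, 0.07 and 0.24 without methionine replicate 1, 2 and 3, and without replicate 3 the medians of the regulators and of peroxide defence were 0.41 and 0.16 (adjusted p = 0.294).

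Among transcripts that fell in low methionine, RCF2, a factor of cytochrome oxidase supercomplexes, had the largest change (-2.40 ± 0.17, adjusted p = 0.000229). ACS1, acetyl-CoA synthetase, fell (-1.78 ± 0.35), as did PDR12, a weak-acid exporter (-1.22 ± 0.21), POT1, the thiolase of beta-oxidation (-1.21 ± 0.17), and CTR1, a copper transporter (-1.17 ± 0.24, and -0.59 with an adjusted p of 0.156 with median centring and -1.38 with 0.0343 with processed signals). ACS1 was the 1 gene of 16 called in gluconeogenesis, the glyoxylate cycle and acetate (1 fell adjusted over the list alone), a list shifted down (median -0.22, camera adjusted p = 0.019, and adjusted p = 0.187 with an estimated correlation). With median centring its median was 0.07 (adjusted p = 0.0775). Other members were ATO3 at -0.59 ± 0.18, CAT2 at -0.35 ± 0.12 and YAT2 at -0.31 ± 0.11. The mitochondrial ribosomal protein list shifted down by a small amount (median -0.17, camera adjusted p = 0.00017, and adjusted p = 0.0396 with an estimated correlation), with 0 of its 65 genes called by limma, 0 adjusted over the list alone and 10 at an unadjusted p under 0.05. With median centring its median was 0.06, below the 0.20 of all genes (adjusted p = 0.0192). Other amino acid synthesis (median 0.16, 1 rose of 51, 1 rose adjusted over the list alone, camera adjusted p = 0.00698, and adjusted p = 0.517 with an estimated correlation) shifted up. So did ergosterol synthesis (median 0.17, 0 of 23 by limma, 0 adjusted over the list alone, 4 at an unadjusted p under 0.05, camera adjusted p = 0.0214, and 0.449 with an estimated correlation). Mating and meiosis (median -0.15, 0 of 13 by limma, 0 adjusted over the list alone, 2 at an unadjusted p under 0.05, camera adjusted p = 0.028, and 0.371 with an estimated correlation) shifted down. The called gene of other amino acid synthesis was HOM2, aspartate semialdehyde dehydrogenase (1.20 ± 0.18), beside HOM3 at 0.80 ± 0.25, HOM6 at 0.74 ± 0.19 and CPA1 at 0.77 ± 0.27. Of the genes with no symbol, KLLA0C00286g rose at least 8.79-fold (3.36 ± 0.34) and KLLA0C18909g at least 6.36-fold (2.97 ± 0.42), while KLLA0A04906g (-2.03 ± 0.36, and -1.31 without methionine replicate 1) and KLLA0B00242g (-0.79 ± 0.16) fell. The median of gluconeogenesis was -0.10 without methionine replicate 2 (adjusted p = 0.0583), and that of mating was -0.26 without methionine replicate 3.

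By limma, 75 of 3557 genes were called in low against high methionine, 59 up and 16 down, of which 49 and 6 changed at least 2-fold, and 505 genes had an unadjusted p under 0.05. With median centring 59 of the 59 and 15 of the 16 kept their direction. It raised bright genes as a class, with a median of 0.70 in the brightest of 5 classes. It could therefore hardly turn the rise of a bright gene, and it is mainly a check on the falls. The size of the rises depended on the processing. The median of the 59 was 1.59 with loess, 2.27 with median centring and 2.48 with processed signals. Of the 33 named calls 26 held with each other scaling and background setting, and CTA1, CTR1, GSH1, OYE2, SHM2, SOD1 and KLLA0B00242g did not. With members not above background in high methionine at their bound, the median was 0.60 for transport and 0.22 for the regulators. Without methionine replicate 1, 2 or 3 the count was 48, 28 and 29. Of the 33 named calls 13 held in each of these fits (CYS3, DUG2, JLP1, MET2, MET3, MET6, MET10, MET14, MUP1, POT1, RCF2, SUL2 and KLLA0C00286g), and 9, 15 and 15 were lost (PRX1 had no value without methionine replicate 3), with an adjusted p up to 0.335 for CTR1 without methionine replicate 2. Without methionine replicate 3 MET17 had an adjusted p of 0.0595, the list of thioredoxin, glutaredoxin and peroxide defence 0.294 and that of gluconeogenesis 0.225, and without methionine replicate 2 gluconeogenesis, ergosterol synthesis and mating had 0.0583, 0.149 and 0.144. Without methionine replicate 1 ergosterol synthesis and mating had 0.0812 and 0.0681.

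**Figure D2:**
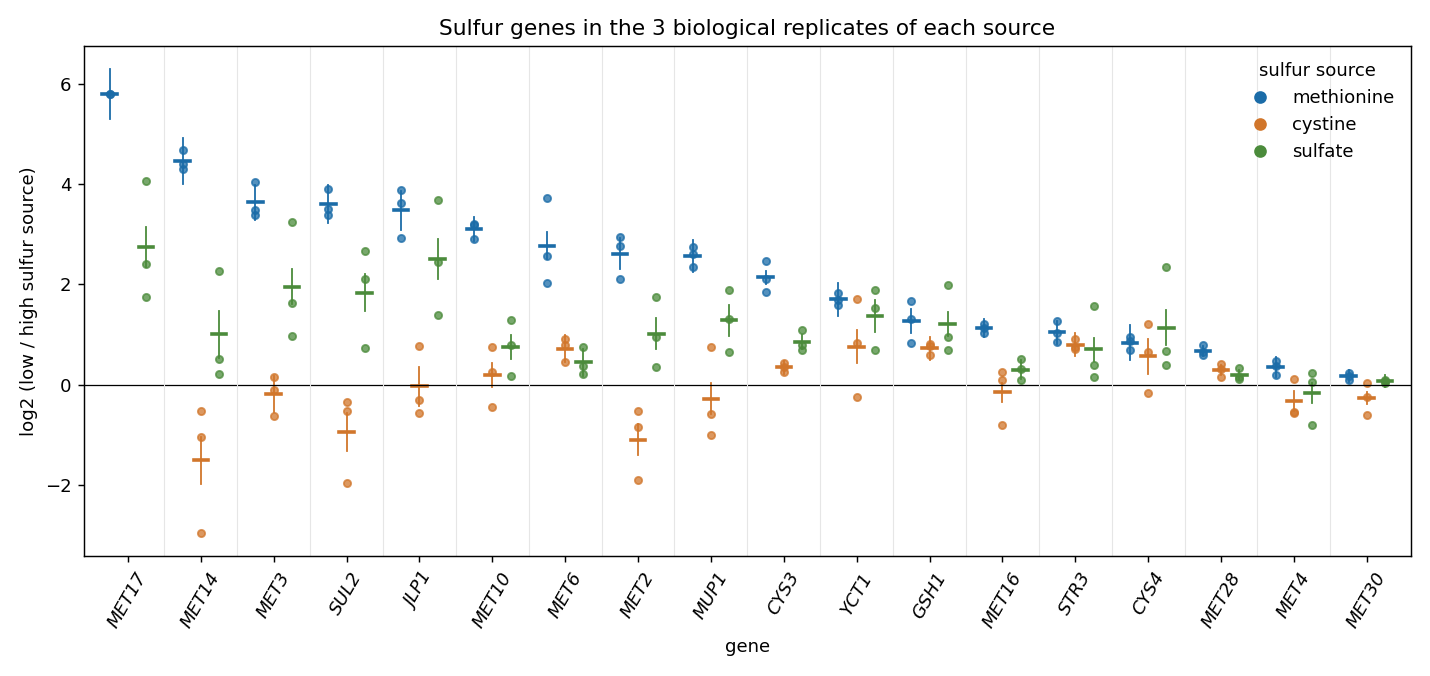
Response of 18 sulfur genes. The vertical axis is the log2 ratio of the low over the high culture, each point is 1 biological replicate of methionine (blue), cystine (orange) or sulfate (green), horizontal bars are means and vertical lines are ±1 standard error of the model. In methionine the bars run from 5.79 for MET17 to 0.17 for MET30 (-0.09 with median centring), and in cystine MET14 (-1.51), MET2 (-1.09), SUL2 (-0.94), MUP1 (-0.28), MET3 (-0.18) and JLP1 (-0.03) lie below 0 with loess and above 0 (0.06, 0.20, 0.56, 0.83, 1.04 and 1.42) with median centring. With median centring the brightest of 5 classes of all genes tested had a median of 0.90 in cystine.

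In low cystine 720 genes were called (0, 30 and 165 without cystine replicate 2, 3 and 1), yet most sulfur genes that rose in low methionine did not pass the test in it. MET14 (-1.51 ± 0.47, adjusted p = 0.049) and MET2 (-1.09 ± 0.30, adjusted p = 0.0377) fell with loess. Their values were 0.06 and 0.20 with median centring, -1.30 and -1.14 with processed signals (adjusted p = 0.0407 and 0.063), and -0.78 and -0.69 without cystine replicate 2 (adjusted p = 0.245 and 0.185). MET3 (-0.18 ± 0.35), JLP1 (-0.03 ± 0.39), MET16 (-0.15 ± 0.18), SUL2 (-0.94 ± 0.37, adjusted p = 0.0949), MUP1 (-0.28 ± 0.31), MET10 (0.19 ± 0.24), CYS3 (0.35 ± 0.13, adjusted p = 0.0824) and MET6 (0.72 ± 0.27, adjusted p = 0.0773) did not pass the test. SUL2 was at -0.34, -1.95 and -0.52 in cystine replicates 1, 2 and 3. With median centring MET3 was at 1.04, JLP1 at 1.42, SUL2 at 0.56 and MUP1 at 0.83. There the brightest of 5 classes of all genes tested had a median of 0.90 in cystine, against -0.13 with loess. Values of this size are therefore no evidence of a rise of these genes. MET3, JLP1, MET16, SUL2 and MUP1 were well above background in both cystine cultures on 6 of 6 arrays, while in high methionine MET3, JLP1, MET16 and SUL2 were above background on 0 of 6. STR3 rose (0.80 ± 0.23, adjusted p = 0.041). Others of the panel were GSH1 at 0.72 ± 0.23 (adjusted p = 0.0553), YCT1 at 0.76 ± 0.32, CYS4 at 0.56 ± 0.35, MET28 at 0.30 ± 0.10, MET4 at -0.33 ± 0.20 and MET30 at -0.27 ± 0.12. The sign differed between cystine replicates 1, 2 and 3 for YCT1 (1.70, 0.83 and -0.25) and CYS4 (-0.17, 0.66 and 1.20). MET17 had no value, because all its cystine spots carried outlier flags.

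Of 22 genes in the citric acid cycle list 7 rose in low cystine. SDH1, a subunit of succinate dehydrogenase, rose 2.37-fold (1.24 ± 0.25), LSC2, of succinyl-CoA ligase, rose 2.10-fold (1.07 ± 0.22), FUM1, fumarase, rose 2.09-fold (1.06 ± 0.13), and MDH2, malate dehydrogenase, rose at least 1.35-fold (0.46 ± 0.12). When adjusted over the list alone 17 rose and 1 fell (median 0.74, camera adjusted p = 0.000226, and adjusted p = 0.672 with an estimated correlation). Ergosterol synthesis also shifted up (median 0.38, 5 of 23 rose, 7 adjusted over the list alone, camera adjusted p = 0.0201, and adjusted p = 0.672 with an estimated correlation), with ERG3 (1.04 ± 0.18), ERG10 (0.77 ± 0.16), ERG1 (0.74 ± 0.14) and CYB5 (at least 1.23-fold, 0.39 ± 0.09). Peroxisome and beta-oxidation genes shifted up (median 0.22, 6 of 18 rose, 7 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.0293, and adjusted p = 0.672 with an estimated correlation), with IDP3 (0.79 ± 0.20), TES1 (0.69 ± 0.11), PEX11 (0.68 ± 0.11) and the catalase gene CTA1 (0.55 ± 0.12). In other amino acid synthesis 8 of 51 genes rose and 1 fell, 7 and 1 adjusted over the list alone (median 0.35, camera adjusted p = 0.00135, and adjusted p = 0.672 with an estimated correlation). They included ILV5 (0.95 ± 0.23) and ILV3 (0.76 ± 0.17) of branched-chain amino acid synthesis, ARO2 (0.54 ± 0.12) and LYS12 (0.50 ± 0.12).

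Among genes with a symbol, the 5 largest rises in low cystine were OPT2, an oligopeptide transporter (1.54 ± 0.31), SHM2 (1.40 ± 0.26), SAH1, S-adenosylhomocysteine hydrolase (1.37 ± 0.29), ALD6, acetaldehyde dehydrogenase (1.34 ± 0.16), and EFT1, translation elongation factor 2 (1.31 ± 0.19). Proteasome genes shifted down (median -0.18, 9 of 35 fell and 1 rose, 9 and 3 adjusted over the list alone, camera adjusted p = 0.0244, adjusted p = 0.672 with an estimated correlation and 0.134 with median centring, which had a median of 0.00). Among them were PUP2 (-0.96 ± 0.17), PRE10 (-0.86 ± 0.17) and RPN6 (-0.81 ± 0.12), at -0.01, -0.18 and -0.65 with median centring, where RPN6 alone of these was called. With processed signals they were at -1.04, -1.01 and -1.47, and each was called. UBI4, polyubiquitin, fell with loess (-1.28 ± 0.22) and was at 0.36 with median centring and -0.92 with processed signals (adjusted p = 0.0516). Of the genes with a symbol, the largest fall with loess was that of ATS1 (-2.34 ± 0.33), followed by the ribosomal protein genes RPS18A (-2.14 ± 0.48), RPL40A (-2.11 ± 0.34), RPL35A (-2.11 ± 0.32) and RPL29 (-2.003 ± 0.37), beside RPS6A (-1.99 ± 0.35) and RPS30A (-1.77 ± 0.31). With median centring RPS6A alone of these was called (-1.08, adjusted p = 0.0463). There ATS1 stood at -0.58 (adjusted p = 0.0722), RPL35A at -0.55, RPS18A at -0.39, RPL29 at -0.27, RPL40A at -0.14 and RPS30A at -0.08. With processed signals each was called: RPS6A at -2.29, RPL35A at -1.98, ATS1 at -1.81, RPS18A at -1.60, RPL29 at -1.52, RPS30A at -1.32 and RPL40A at -1.09. The list of cytosolic ribosomal proteins was shifted down with loess (median -0.30, 17 of 56 fell and 2 rose, 19 and 3 adjusted over the list alone, camera adjusted p = 0.00222), but up with median centring (median 1.33). It was not called with Agilent's processed signals (median 0.0984, adjusted p = 0.467) or with an estimated correlation (adjusted p = 0.672). Its median was -0.45 and -0.13 without cystine replicate 2 and 3 (adjusted p = 0.000194 and 0.229), and that of the proteasome was -0.11 without cystine replicate 2 (adjusted p = 0.133). Of the genes with no symbol, KLLA0C05764g (1.36 ± 0.23) and KLLA0B13002g (1.27 ± 0.30) rose, and KLLA0E13069g (-2.48 ± 0.31) fell. KLLA0D17952g fell with loess (-2.42 ± 0.57), but not by the test with median centring (-0.09, adjusted p = 0.8) or with processed signals (-0.55, adjusted p = 0.219).

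By limma, 720 of 3555 genes were called in low against high cystine, 338 up and 382 down, of which 28 and 135 changed at least 2-fold, and 1442 genes had an unadjusted p under 0.05. With median centring 338 of the 338 and 325 of the 382 kept their direction, but 695 genes were called up and 96 down. The brightest of 5 classes had a median of 0.90 there, so rises of bright genes could hardly turn. The median of the 338 rises was 0.64 with loess, 0.78 with median centring and 1.44 with processed signals. Of the 39 named calls 22 held with each other scaling and background setting, which leaves out MDH2, CYB5, ILV3, ILV5 and LYS12 among those that rose. With members at their bound the median of ergosterol synthesis was 0.32. The count varied with the replicates used. It was 165, 0 and 30 without cystine replicate 1, 2 and 3, and 1273 without sulfate replicate 3. Without cystine replicate 2, 1018 genes had an unadjusted p under 0.05 by limma, and the 39 named calls had an adjusted p of 0.0751 to 0.245. A fit on fewer replicates has less power, so a lost call need not mean a changed size. Without cystine replicate 2 ALD6 stood at 1.30, against 1.34 with all replicates, and ILV5 at 0.67, against 0.95. Leaving out cystine replicate 1 or 3 ended 15 and 34 of the named calls, and it ended the list calls of peroxisome and beta-oxidation (adjusted p = 0.0705 and 0.0605). The ribosomal protein list had an adjusted p of 0.229 without cystine replicate 3 and the proteasome list 0.133 without cystine replicate 2.

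**Figure D3:**
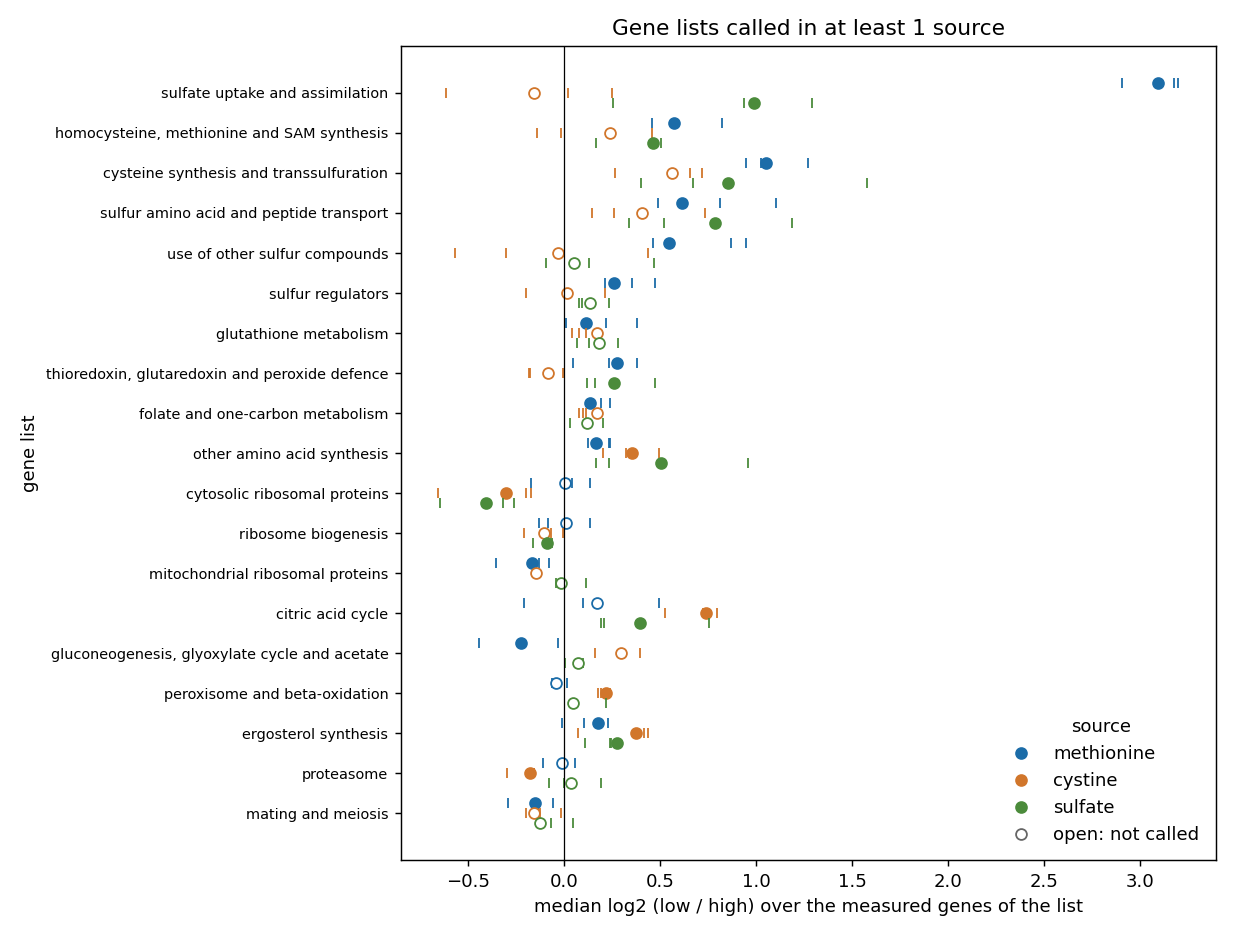
The 19 gene lists called in at least 1 source. The horizontal axis is the median log2 ratio of the low over the high culture over the measured genes of a list, circles are medians for methionine (blue), cystine (orange) and sulfate (green), filled where the list was called, and ticks are the medians of the 3 replicates. Sulfate uptake and assimilation stands at 3.09 in methionine, -0.15 in cystine and 0.99 in sulfate, and the cytosolic ribosomal proteins stand at -0.30 in cystine and -0.41 in sulfate, which turn to 1.33 and 1.87 with median centring.

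In low sulfate some of the same sulfur genes rose. MET17 rose 6.69-fold (2.74 ± 0.40, adjusted p = 0.0441), MET3 rose (1.95 ± 0.35, adjusted p = 0.0397, above background in high sulfate on 1 of 6 arrays), and CYS3 rose 1.81-fold (0.85 ± 0.13, adjusted p = 0.0337). JLP1, not above background in high sulfate, also rose (2.51 ± 0.39). SUL2 (1.84 ± 0.37, adjusted p = 0.0597), GSH1 (1.21 ± 0.23, adjusted p = 0.051), YCT1 (1.37 ± 0.32, adjusted p = 0.0847) and MUP1 (1.29 ± 0.31, adjusted p = 0.0883) were above 0 in 3 of 3 replicates but did not pass the test. Other panel genes were CYS4 (not above background in high sulfate) at 1.14 ± 0.35, MET2 at 1.02 ± 0.30, MET14 at 1.00 ± 0.47, MET10 at 0.75 ± 0.24, and STR3 at 0.71 ± 0.23. The mean of CYS4 rested on sulfate replicate 3 (0.40, 0.67 and 2.34 in replicates 1, 2 and 3). Nearer to 0 were MET6 at 0.44 ± 0.27, MET16 at 0.30 ± 0.18, MET28 at 0.20 ± 0.10, MET30 at 0.07 ± 0.12 and MET4 at -0.17 ± 0.20, of which MET30 (-0.02 with median centring) and MET4 (0.07 with an equal spread of every array) turned.

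As a list, sulfate uptake and assimilation was shifted up (median 0.99, 1 of 7 rose, 5 adjusted over the list alone, camera adjusted p = 1.4e-05, and adjusted p = 0.12 with an estimated correlation), with MET1 at 0.99 ± 0.26 and MET22 at 0.50 ± 0.13. Sulfur amino acid and peptide transport was shifted up with 0 of 8 genes called by limma, 6 adjusted over the list alone and 6 at an unadjusted p under 0.05 (median 0.78, camera adjusted p = 0.00156, and adjusted p = 0.12 with an estimated correlation). Among its members were AGP3 at 0.79 ± 0.25 and SAM3 at 0.46 ± 0.17. Homocysteine, methionine and SAM synthesis was shifted up (median 0.47, 1 of 8 rose, 3 adjusted over the list alone, camera adjusted p = 0.0158, and adjusted p = 0.12 with an estimated correlation), with SAM4 at 0.50 ± 0.11. Cysteine synthesis and transsulfuration was shifted up (median 0.85, 1 of 3 rose, 3 adjusted over the list alone, camera adjusted p = 0.000935), also with an estimated correlation (adjusted p = 0.00708). The list of thioredoxin, glutaredoxin and peroxide defence was shifted up (median 0.26, 3 of 19 rose, 4 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.00625, and adjusted p = 0.281 with an estimated correlation). The 3 were PRX1 (1.81 ± 0.22, n = 2), SOD1 (1.05 ± 0.18) and OYE2 (0.91 ± 0.17). Its member CTT1, a catalase, was at -0.74 ± 0.17 with loess (adjusted p = 0.0807) and at 1.32 with median centring. Replicate 3, whose unswapped array stood apart, weighed on these lists: without it the median was 0.55 for sulfate uptake and assimilation, 0.49 for transport, 0.54 for cysteine synthesis and 0.17 for peroxide defence, with the 4 still called.

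Metabolic lists also shifted in low sulfate, by amounts that rested on sulfate replicate 3. Other amino acid synthesis (median 0.50, camera adjusted p = 6.7e-07, and 0.284 with an estimated correlation), the citric acid cycle (median 0.39, camera adjusted p = 0.00625, and 0.52) and ergosterol synthesis (median 0.28, camera adjusted p = 0.0158, and 0.52) were shifted up. By limma 0 of 51, 0 of 22 and 0 of 23 genes were called, 1, 0 and 0 rose adjusted over the list alone, and 29, 7 and 7 had an unadjusted p under 0.05. Their members included HOM2 at 0.96 ± 0.18 (adjusted p = 0.051), ILV2 at 1.35 ± 0.38, ARG1 at 0.72 ± 0.18, and TRP1 at 0.55 ± 0.15 of amino acid synthesis. Those of the citric acid cycle list were IDH1 at 1.10 ± 0.32, LSC1 at 0.98 ± 0.31, IDP1 at 0.97 ± 0.29 and MDH3 at 0.60 ± 0.23. Those of ergosterol synthesis were ERG13 at 0.83 ± 0.26, ERG2 at 0.74 ± 0.23, ERG6 at 0.63 ± 0.19 and ERG10 at 0.56 ± 0.16. Without that replicate the medians were 0.21, 0.22 and 0.16, with the 3 lists still called. Its values were the highest of the 3 replicates for IDH1 (0.50, 0.57 and 2.22), LSC1 (0.60, 0.46 and 1.88), IDP1 (0.28, 0.60 and 2.03), MDH3 (0.20, 0.18 and 1.43) and ILV2 (0.49, 0.82 and 2.75). COR1, a core subunit of the cytochrome bc1 complex, rose (0.98 ± 0.13, adjusted p = 0.0256).

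RCF2 fell in low sulfate 5.44-fold (-2.44 ± 0.17, adjusted p = 0.000398), and of the 23 genes that fell with loess it alone stayed below 0 with median centring (-0.49, adjusted p = 0.282). With processed signals it was at -2.80 (adjusted p = 0.00011). The ribosomal protein genes RPL29 (-2.22 ± 0.37), RPL35A (-1.93 ± 0.32), RPL37A (-1.79 ± 0.26) and RPL31B (-1.56 ± 0.16), DPI8 (-2.08 ± 0.36) and GAL7, of galactose use (-1.88 ± 0.27), fell with loess. They stood at 0.56, 0.45, 1.16, 1.62, 0.32 and 0.47 with median centring. There the brightest of 5 classes of all genes tested had a median of 1.18 in sulfate, against 0.01 with loess. For a bright gene a value above 0 there is therefore no evidence against a fall. With processed signals RPL29 (-1.43), RPL35A (-1.72), DPI8 (-1.85) and GAL7 (-1.47) were called. RPL37A (-0.76, adjusted p = 0.151) and RPL31B (-0.23, adjusted p = 0.663) were not. The list of cytosolic ribosomal proteins was shifted down with loess (median -0.41, 6 of 57 fell, 20 fell and 1 rose adjusted over the list alone, camera adjusted p = 3.0e-12, and adjusted p = 0.0263 with an estimated correlation). It was shifted up with median centring (median 1.87) and not called with Agilent's processed signals (median 0.107, adjusted p = 0.261). Ribosome biogenesis was shifted down by a small amount (median -0.09, 0 of 47 by limma, 0 adjusted over the list alone, 3 at an unadjusted p under 0.05, camera adjusted p = 0.00716, and adjusted p = 0.52 with an estimated correlation). Its members included DBP10 at -1.01 ± 0.28 (0.32 with median centring and -1.30 with processed signals), ENP1 at -0.56 ± 0.20, UTP22 at -0.44 ± 0.17 and ARX1 at -0.27 ± 0.13, and without sulfate replicate 3 its median was -0.04. Of the genes with no symbol, KLLA0C18909g rose at least 4.76-fold (2.39 ± 0.42) and KLLA0C01562g rose (1.77 ± 0.24, above background in high sulfate on 2 of 6 arrays). KLLA0E05127g (-1.47 ± 0.23) and KLLA0E11661g (-1.14 ± 0.20) fell with loess and stood at 1.43 and 1.95 with median centring and at -0.49 and 0.07 with processed signals.

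**Figure D4:**
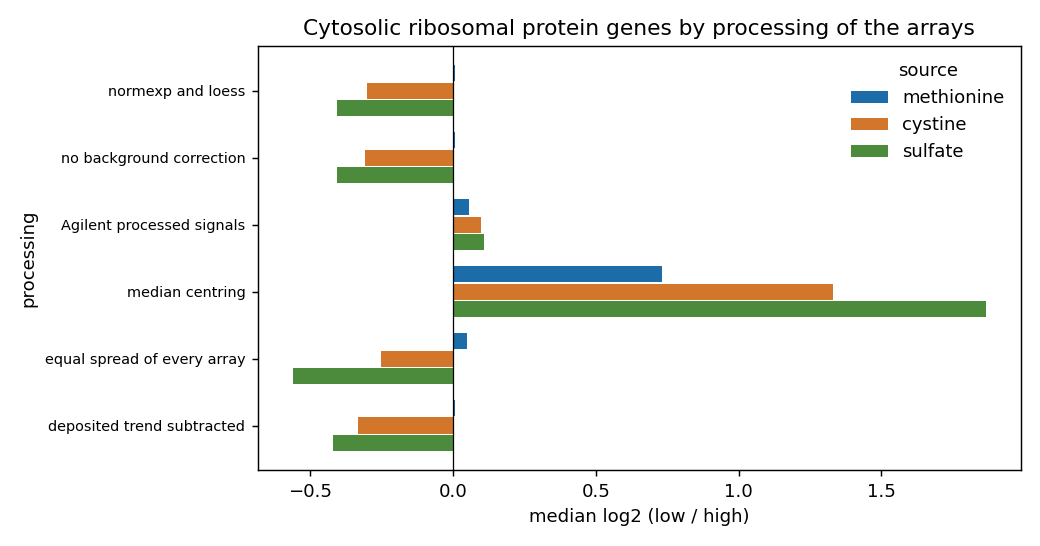
Cytosolic ribosomal protein genes under 6 ways to process the arrays. Bars give the median log2 ratio of the low over the high culture over the genes of the list, for methionine (blue), cystine (orange) and sulfate (green). With normexp and loess the medians are 0.01, -0.30 and -0.41, and with median centring they are 0.73, 1.33 and 1.87. With median centring the brightest of 5 classes of all genes tested had medians of 0.70, 0.90 and 1.18.

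By limma, 34 of 3559 genes were called in low against high sulfate, 11 up and 23 down, of which 8 and 20 changed at least 2-fold, and 653 genes had an unadjusted p under 0.05. With median centring 11 of the 11 and 1 of the 23 kept their direction. The brightest of 5 classes had a median of 1.18 there, so rises of bright genes could hardly turn. The median of the 11 rises was 1.77 with loess, 2.96 with median centring and 3.63 with processed signals. Of the 23 falls 21 kept their direction with processed signals and 23 with the other 3 settings. With members not above background at their bound the median was 0.53 for transport, 0.13 for thioredoxin, glutaredoxin and peroxide defence, 0.32 for other amino acid synthesis, 0.37 for the citric acid cycle and 0.20 for ergosterol synthesis. The count was 11 without sulfate replicate 1, 1 without sulfate replicate 2 and 2 without sulfate replicate 3. Among the 19 named calls RCF2 alone held in each of these fits, while 13, 18 and 17 were lost with an adjusted p of up to 0.217 (PRX1 without sulfate replicate 2). It was 22 and 68 without methionine replicate 1 and 2, and 15, 21 and 12 without cystine replicate 1, 2 and 3, which share the estimate of the spread. Without sulfate replicate 2 homocysteine, methionine and SAM synthesis had an adjusted p of 0.123 and ergosterol synthesis 0.0569 (median 0.18).

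The sources were then compared with each other, to see which responses were shared and which differed, with the caution that their concentrations differed. Between methionine and sulfate 10 genes rose in both, where independent lists would share 0.182 (Fisher's exact test, adjusted p = 2.3e-17), among them CYS3, JLP1, MET3, MET17, OYE2, PRX1 and SOD1. Genes are not independent, and the sources share 1 estimate of the spread per gene. The exact tests of overlap given here may therefore overstate the evidence. Of the 59 genes that rose in low methionine, 58 lay above 0 in low sulfate, with a median of 0.99, and 38 of 58 lay above 0 in low cystine, with a median of 0.17. Between cystine and sulfate 21 genes fell in both, where 2.47 would be shared (Fisher's exact test, adjusted p = 3.4e-18), among them RPL29, RPL31B, RPL35A, RPL37A, UBI4, GAL7, DPI8, ATS1 and RCF2, but with median centring 12 of the 21 stayed below 0 in cystine and 1, RCF2, in sulfate. With the other 4 settings 21 of the 21 stayed below 0 in both. With median centring the brightest of 5 classes of all genes tested had medians of 0.90 in cystine and 1.18 in sulfate. Methionine and cystine shared 5 rising genes, near the 5.51 of independent lists (Fisher's exact test, adjusted p = 1), and 3 falling genes (adjusted p = 0.294). Methionine and sulfate shared 1 falling gene (exact test, adjusted p = 0.198), and cystine and sulfate shared 2 rising genes (exact test, adjusted p = 0.294). In all, 15 genes rose and 23 fell in more than 1 source. PRX1 was called up in each source, but on 1 replicate in methionine, 2 in cystine and 2 in sulfate. RCF2 fell in all 3 with loess, by 1.06 in cystine, where it was at 0.07 with median centring.

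That count of 38 genes was 25 and 64 without methionine replicate 1 and 2, 14, 6 and 5 without cystine replicate 1, 2 and 3, and 20, 3 and 24 without sulfate replicate 1, 2 and 3. Across all genes the responses correlated between methionine and cystine (Pearson r = 0.384, Spearman rho = 0.553), methionine and sulfate (0.611 and 0.538) and cystine and sulfate (0.655 and 0.645). Genes are not independent replicates, so no p is given for these 3 correlations.

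The direct test found 36 genes whose response differed between methionine and cystine by limma, 28 higher in methionine and 8 lower, of which 26 and 7 differed at least 2-fold, and 485 had an unadjusted p under 0.05. The difference was 5.96 ± 0.66 for MET14 and 3.70 ± 0.43 for MET2 (adjusted p = 0.00749 for both). Both were above background in high methionine on 3 of 6 arrays, so these are no exact sizes. SUL2, MET3 and KLLA0F05775g, which has no symbol, were not above background in high methionine, so their fitted differences of 4.54 ± 0.53, 3.82 ± 0.50 and 5.15 ± 0.69 (adjusted p = 0.00749, 0.0163 and 0.0164) are no measure of size. With median centring they were 3.64, 3.19 and 4.26 (adjusted p = 0.0135, 0.0135 and 0.047). In the other direction it was -1.51 ± 0.24 for ALD4, mitochondrial acetaldehyde dehydrogenase, -1.43 ± 0.24 for POT1, -1.39 ± 0.23 for COX15, of heme A synthesis, -1.35 ± 0.24 for RCF2 and -1.29 ± 0.22 for KLLA0E09021g. These 5 were not called with median centring (adjusted p = 0.241, 0.0957, 0.104, 0.13 and 0.273), where the differences were -1.13, -1.12, -1.35, -1.74 and -1.05. With processed signals POT1 alone was called (-2.89, adjusted p = 0.0228), beside ALD4 at -2.43, COX15 at -1.90, RCF2 at -1.45 and KLLA0E09021g at -2.41. Of the other panel genes, MET10 (2.91 ± 0.34), MET6 (2.05 ± 0.38) and CYS3 (1.79 ± 0.19) also had a higher ratio in methionine. In high cystine their mean log2 levels were 8.57, 8.91 and 8.95, against 6.40, 7.70 and 7.46 in high methionine. For MET14, SUL2 and MET2 they were 11.4, 10.7 and 10.1, against 6.22, 5.98 and 6.34. In high methionine MET14, SUL2 and MET2 were above background on 3, 0 and 3 of 6 arrays, so their levels there lay near the background. Levels of different arrays were not tested against each other. A level already high in high cystine thus cannot be told apart from a weaker response to low cystine. JLP1 and MUP1, above background in high methionine on 0 and 1 of 6 arrays, also had a higher ratio in methionine. With loess 3 genes rose in methionine and fell in cystine, MET14, MET2 and KLLA0F05775g, and 2 fell in methionine and rose in cystine, CTA1 among them. MET14 and MET2 were at 0.06 and 0.20 in cystine with median centring and at -1.30 and -1.14 with processed signals. The count of 36 was 12, 85 and 1 without methionine replicate 1, 2 and 3, 13 and 6 without cystine replicate 1 and 2, and 168 without sulfate replicate 3. Without methionine replicate 3 each of the 10 leading genes missed the threshold, MET14, MET2 and SUL2 at an adjusted p of 0.0533. The differences of these 3 were 6.04, 3.53 and 4.38 there, so the calls were lost with little change in size.

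No gene differed between methionine and sulfate by limma (0 called, 190 with an unadjusted p under 0.05) or between cystine and sulfate (0 called, 373 with an unadjusted p under 0.05). The smallest adjusted p was 0.0798 in the first comparison, shared by MET10 (2.34 ± 0.34) and CYS3 (1.28 ± 0.19), and in the second 0.219, shared by SUL2 (-2.77 ± 0.53) and MET2 (-2.11 ± 0.43). A single gene passed between methionine and sulfate without methionine replicate 1.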

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

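Of the tests reported in this part, the tests of within-array normalization on the ribosomal protein genes and on the sulfur genes, the test of dim arrays on the genes not above background, and the fit without the unswapped array of sulfate replicate 3 were chosen only after the result was seen.

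The unswapped arrays of 2 replicates stood apart from the others of their source. On the unswapped array of cystine replicate 3 the red negative controls had a median of 110.3, against 47.9 to 52.2 on the other 5 cystine arrays. On the unswapped array of sulfate replicate 3 they had a median of 282, against 51.8 to 60.8. The same sulfate array correlated with the other sulfate arrays at a mean r of 0.312, against 0.619 to 0.678 for the others, and its log2 ratios had a standard deviation of 1.25, against 0.296 to 0.455. Dixon's test set these 4 values apart in 18 tests of 6 arrays each, on several measures of each source. Its chance rate is about 1 test in 20. The tests use the same arrays and the arrays are dye-swapped pairs, so this rate may not hold here. Without this sulfate array 83 genes were called in low sulfate, in place of 34.

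The response to low sulfur differed between methionine and cystine for 36 genes by the test of the difference itself, 28 higher in methionine. Without methionine replicate 3 the count was 1, and it was 12 and 85 without methionine replicate 1 and 2, 13 and 6 without cystine replicate 1 and 2, and 168 without sulfate replicate 3. The differences on the log2 scale were 5.96 for MET14, 5.15 for KLLA0F05775g, 4.54 for SUL2, 3.82 for MET3 and 3.70 for MET2. MET14 and MET2 were above background in high methionine on 3 of 6 arrays, so theirs are no exact sizes. KLLA0F05775g, SUL2 and MET3 were not above background in high methionine, so these values are no measure of size, and with median centring they were 4.26, 3.64 and 3.19. In the other direction they were -1.51 for ALD4, -1.43 for POT1, -1.39 for COX15, -1.35 for RCF2 and -1.29 for KLLA0E09021g. The 2 sources also differed in concentration, 10 mM and 10 µM against 1 mM and 1 µM, so the tests do not separate the kind of sulfur source from its amount. Nor do they separate a level already high in high cystine from a weaker response to low cystine. MET14 stood at a mean log2 level of 11.4 in high cystine and 6.22 in high methionine.

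The first pattern is the fall of the cytosolic ribosomal protein genes in low cystine and low sulfate (medians -0.30 and -0.41 with loess). The tables argue against gene length, because among random lists matched on length the list lay at percentile 0.01 in cystine and lower in sulfate, and against a dye effect, because the highest of the 4 medians by source and dye orientation was -0.22. Spot brightness and within-array normalization stay open and may account for the fall. Among random lists matched on brightness the list lay at percentile 24.1 in cystine and 9.36 in sulfate, and all 57 genes were in the brightest of 5 classes. With median centring the list stood at 1.33 in cystine and 1.87 in sulfate. All genes had a median of 0.09 and 0.11 there, but the brightest class had 0.90 and 1.18, so much of the shift was common to bright genes. The direction of the list's change in these cultures is therefore not known.

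The second pattern is a joint fall in low sulfate of 120 genes that fell at least 2-fold in low cystine, with a median of -0.72 and 112 of 120 below 0 with loess. The set leaves out the cytosolic ribosomal protein genes and the sulfur lists apart from glutathione. Whether its genes share a function was not tested. The tables argue against probe base composition as the whole cause, since the median was -0.49 after regression on it, and against spot brightness, since among random sets matched on brightness the median lay at percentile 0. Those random sets had a median of 0.15 with loess, so the set fell relative to equally bright genes there. Within-array normalization stays open for the direction against 0. With median centring the median in low sulfate was 0.36 and 10 of the 120 genes lay below 0, against a median of -0.88 with Agilent's processed signals. With median centring the brightest of 5 classes of all genes tested had a median of 1.18 in sulfate, and no matched sets were drawn. In low methionine the set had a median of -0.54 with loess and 0.07 with median centring. A shared biological response to low sulfur also stays open and was not tested.

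The third pattern is the smaller rise in low sulfate than in low methionine of 16 genes of sulfate assimilation, methionine and cysteine synthesis, with replicate medians of 0.22, 0.71 and 0.76 against 1.49, 1.57 and 1.52. For the 7 of them well above background in both sulfate cultures, the highest replicate median in sulfate was 0.96 against 2.77 as the lowest in methionine. With median centring these were 2.20 and 2.89. Over these 7 genes the rise was thus smaller in sulfate without a dim signal. The 7 were picked by their signal in the sulfate cultures, with no such filter in methionine. This favours genes already present in high sulfate, which can rise less there. The contrast therefore does not decide on dim arrays or within-array normalization for the 16 genes. Without the array with raised red negative controls the highest replicate median of the 16 genes in sulfate was 0.71, which argues against that array. For the other 9 genes, with a highest replicate median of 0.83 in sulfate, dim arrays cannot be told apart from a smaller rise, and within-array normalization stays open for the 16, since with median centring their highest replicate median in sulfate was 1.62, against 1.54 as the lowest in methionine. The scan session cannot be told apart from the source, since 0 sessions held both methionine and sulfate arrays, and the kind and concentration of the sulfur source stay open, untested, as candidate explanations.

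The splits were too few for a share under 0.05. Of the 4 sign patterns of 3 replicates, 1, the real one, gave as many genes in methionine (75, highest other 0), in cystine (720, highest other 0) and in sulfate (34, highest other 0). Of the 10 splits of 6 replicates, 1 gave as many genes between methionine and cystine (36, highest other 0). By limma 0 genes differed between methionine and sulfate (190 at an unadjusted p under 0.05, highest other split 0) and 0 between cystine and sulfate (373 at an unadjusted p under 0.05, highest other split 1), so 10 of the 10 splits gave as many.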

How the results depend on the processing

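The tests with array quality weights, with outlier-marked spots kept, with single slides and without single arrays were chosen only after the results were seen. Unless a reason is given, the cause of a change was not tested.

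Counts are given as methionine, cystine and sulfate where 3 stand together, against 75, 720 and 34 genes, 36 genes that differed between methionine and cystine, 0 by limma between methionine and sulfate (190 at an unadjusted p under 0.05), 0 between cystine and sulfate (373 likewise) and 38 genes changed in more than 1 source. Total counts that are not listed stayed within 1.5 times these. Without background correction 53 genes changed in sulfate, 5 differed between methionine and sulfate and 111 between methionine and cystine, and 62 changed in more than 1 source. With Agilent's processed signals 319 changed in sulfate (257 up, 62 down), 1 differed between methionine and sulfate and 25 between cystine and sulfate, and 151 changed in more than 1 source. With median centring 219 changed in methionine (208 up, 11 down), 791 in cystine (695 up, 96 down, against 338 and 382 with loess, with 342 genes in common) and 722 in sulfate (722 up, 0 down), 9 differed between methionine and cystine, and 552 changed in more than 1 source. Median centring put the median of all genes at 0.20 in methionine, 0.09 in cystine and 0.11 in sulfate, and the processed signals put it at 0.19 in sulfate. With an equal spread of every array 281 changed in methionine (154 up, 127 down, against 59 and 16) and 331 in sulfate (133 up, 198 down), 5 differed between methionine and sulfate and 158 between methionine and cystine, and 326 changed in more than 1 source.

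Signal over background limited what could be tested, most of all in sulfate. Without the brightness filter 2 genes changed in sulfate and 7 in more than 1 source. The strict filter tested far fewer genes, because few were bright in every array, and called 14, 198 and 119 genes (4, 16 and 7 up), 9 between methionine and sulfate, and 107 in more than 1 source. With fewer arrays or replicates, each source fitted alone gave 6 genes in sulfate and 20 in more than 1 source. Arrays with the high culture in Alexa647 gave 19, 220 and 6 genes, 1 between methionine and cystine and 7 in more than 1 source. Arrays with it in Alexa555 gave 115 in methionine and 58 in sulfate, 1 between methionine and sulfate, 118 between methionine and cystine, and 65 in more than 1 source. Slide 2 alone gave 45 in methionine, 140 in cystine and 9 between them.

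All 18 arrays in 1 fit gave 114, 1125 and 144 genes, with 13, 22 and 157 between methionine and sulfate, cystine and sulfate, and methionine and cystine, and 139 in more than 1 source. With slide as a block 1101 changed in cystine and 141 in sulfate, 10, 18 and 147 differed in the same order, and 136 changed in more than 1 source. With array quality weights 1664 changed in cystine and 459 in sulfate, 24, 208 and 345 differed, and 372 changed in more than 1 source. The deposited trend gave 56 in sulfate, 1 between methionine and sulfate, 104 between methionine and cystine and 65 in more than 1 source. Without the unswapped array of sulfate replicate 3, 83 changed in sulfate, 4 differed between methionine and sulfate and 96 changed in more than 1 source. With the replicate number as a block, 76, 550 and 32 genes changed, although the numbers pair no replicates.

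Leaving out 1 replicate each gave 28 (without methionine replicate 2) to 89 (without sulfate replicate 3) genes in methionine, 0 by limma (without cystine replicate 2, 1018 at an unadjusted p under 0.05) to 1273 (without sulfate replicate 3) in cystine and 1 (without sulfate replicate 2) to 68 (without methionine replicate 2) in sulfate. Between sources it gave 0 to 1 (methionine and sulfate, 1 without methionine replicate 1), 0 to 0 (cystine and sulfate) and 1 (without methionine replicate 3) to 168 (without sulfate replicate 3, methionine and cystine). In more than 1 source it gave 3 (without sulfate replicate 2) to 64 (without methionine replicate 2). Where 1 replicate is gone the others of its source stand on 2, with a spread pooled over the sources.

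Of 34 lists, 14, 6 and 10 were called. With an estimated correlation 8, 0 and 2 were, with the strict filter 1, 1 and 2 (of fewer lists, since it left fewer genes), with median centring 14 in cystine and 16 in sulfate, and with processed signals or with weights 3 in cystine. Limma's fry called 10, 1 and 1. Leaving out 1 replicate gave 12 to 15, 4 to 6 and 8 to 11. Of 785 values of called lists under an alternative, 725 kept direction and call, 56 lost the call and 4 reversed. Those 4 were the ribosomal proteins with median centring (1.33 in cystine and 1.87 in sulfate) and, relative to the other genes under the strict filter, the ribosomal proteins in cystine (median -0.26) and ribosome biogenesis in sulfate (median -0.31).

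Of 1469 values of named genes, 1066 kept direction and side of the threshold, 260 lost the call, 111 gained it, 15 with a call reversed, and 17 with no call in either fit turned sign. With median centring the values were 1.42 for JLP1, 0.058 for MET14, 0.20 for MET2, 1.04 for MET3 and 0.36 for UBI4 in cystine. In sulfate they were 1.32 for CTT1, 0.32 for DPI8, 0.47 for GAL7, 0.56 for RPL29, 1.62 for RPL31B, 0.45 for RPL35A, 1.16 for RPL37A, 1.43 for KLLA0E05127g and 1.95 for KLLA0E11661g (0.073 with processed signals). Of the named calls, 26 of 33 in methionine, 22 of 39 in cystine, 10 of 19 in sulfate and 5 of 10 between methionine and cystine held under each of 4 settings (no background correction, processed signals, median centring and equal spread). Of these, 13, 0, 0 and 0 held also in every fit without 1 replicate of the source or sources concerned. Named calls were not followed in the fits without a replicate of another source. A choice among several probes of a gene and a grade of similarity of list members could not be run, since each gene had 1 probe and no grade was held.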

Other observations

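The tests of lists on the differences between sources were chosen only after the results were seen. All list values are median log2 ratios with camera adjusted p values.

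The lists that no source called were iron-sulfur cluster assembly, iron and copper uptake and iron regulon, methionine and aromatic amino acid catabolism (the Ehrlich pathway), methionine salvage and polyamines, thiamine and biotin, purine synthesis, nitrogen catabolism and ammonium, general stress response, chaperones and heat shock, glycolysis and ethanol formation, the respiratory chain and ATP synthase, phosphate, autophagy, histones, and lactose and galactose use. Their medians ran from -0.07 to 0.22 in methionine, -0.12 to 0.36 in cystine and -0.06 to 0.41 in sulfate, each highest for glycolysis. Their smallest adjusted p was 0.103 in methionine (shared by methionine salvage and polyamines, where 2 of 10 genes rose, and nitrogen catabolism, where 1 of 22 rose), 0.183 in cystine (nitrogen catabolism, 4 of 22 genes rose) and 0.242 in sulfate (glycolysis).

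In cystine these sulfur lists were not called: sulfate uptake and assimilation (median -0.15, adjusted p = 0.89), homocysteine, methionine and SAM synthesis (0.24, adjusted p = 0.772), cysteine synthesis (0.56, adjusted p = 0.237), transport (0.41, adjusted p = 0.292), other sulfur compounds (-0.03, adjusted p = 0.753), regulators (0.02, adjusted p = 0.89) and glutathione (0.17, adjusted p = 0.89). In sulfate, other sulfur compounds (0.05, adjusted p = 0.149), regulators (0.13, adjusted p = 0.534) and glutathione (0.18, adjusted p = 0.0562) were not called.

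Between methionine and cystine 12 lists differed, 5 of them also with an estimated correlation. These were sulfate uptake and assimilation (2.91, adjusted p = 1.2e-23, estimated 1.2e-05), use of other sulfur compounds (1.83, adjusted p = 0.000211, estimated 0.0121), cysteine synthesis (0.27, adjusted p = 0.000864, estimated 0.00368), gluconeogenesis (-0.51, adjusted p = 7.8e-05, estimated 0.0113) and peroxisome and beta-oxidation (-0.27, adjusted p = 7.8e-05, estimated 0.00324). The citric acid cycle was lower in methionine (-0.61, adjusted p = 7.8e-05), but not with an estimated correlation (adjusted p = 0.229). Between methionine and sulfate 11 lists differed, 6 also with an estimated correlation, among them sulfate uptake and assimilation (1.68, adjusted p = 1.2e-16, estimated 0.000694) and gluconeogenesis (-0.32, adjusted p = 0.00151, estimated 0.0399). Limma's fry called 6 lists between methionine and cystine, 0 between methionine and sulfate (smallest adjusted p = 0.159) and 0 between cystine and sulfate (0.269). The ribosomal protein list differed between methionine and sulfate by 0.46 with loess and by -1.02 with median centring. Between cystine and sulfate 4 lists differed, none with an estimated correlation, the first being sulfate uptake and assimilation (-0.80, adjusted p = 0.00016, estimated 0.297).

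With spots kept that carried outlier flags, MET17 had a value in cystine (0.44, limma adjusted p = 0.259), against 5.84 in methionine and 2.54 in sulfate. PRX1 then stood at 3.62, 0.78 and 2.19 in methionine, cystine and sulfate.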
